A study of Homo sapiens with 33 samples.

How the data were processed

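RNA of DLD-1 cells was sequenced in 33 libraries after a TruSeq total RNA preparation, as the labels state. The labels form 11 groups of 3 libraries, by line, auxin and hours of auxin. The protocol gives the times of auxin as 2 or 3 h and 8 or 10 h, while the sample titles of the RanBP2 line give 4 h and 10 h, and the times of the titles are used. The labels do not state that the 3 libraries of a group come from separate cultures, so the p-values measure the spread between the libraries of a group.

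The deposited values are raw read counts per Ensembl gene with no normalization, 1 file per library. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.6.1, featureCounts 1.6.3 and the GRCh38 assembly were used, and their settings, the strand of counting, the handling of reads with several matches and the annotation release are not given in the sources used here. The counts of genes that overlap on opposite strands or share exons with a paralog are therefore uncertain. Of the 58051 gene IDs 57447 were matched by ID to GENCODE release 29 for symbol, position, type and exon number, and the 604 others hold 0.187% of the reads. Positions are on GRCh38.

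The depth per library, from 20.9 to 38.16 M counted reads, is the sum over all genes. Counting intervals and floors cover counting error only. Where all libraries of a group held 0 reads, the fold is a bound against 3 reads over the group, and with few reads the ratio has an exact 95% interval from the binomial split of the reads. CPM are read counts scaled to TMM-adjusted library totals, and values are given as mean ± SD with 3 libraries per group unless SE is stated. Log2 changes are given ± SE, which was derived from the test as the absolute log2 change divided by the square root of edgeR's F statistic.

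Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes kept by filterByExpr, 22167 in number, were scaled by TMM and fitted with glmQLFit (robust) over all 33 libraries with 1 coefficient per group. Each comparison used edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes kept, at an adjusted p under 0.05, and the number changed at least 2-fold is given beside the count. A gene is said to rise or fall where it passes this threshold. There were 10 comparisons within a line and 4 differences between lines, each difference tested as an interaction in the same fit. Genes changed in all 3 degron lines at the late time were counted beside the number that independent lists of the same sizes would share and, added after the data were seen, the number expected given the genes that the NUP214 and NUP88 lines share. The biological coefficient of variation was 11.8%, with 22 residual degrees of freedom and a median prior of 9.15.

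Gene lists, 34 in number with 895 genes of which 894 matched an ID, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. A list needed at least 5 measured members. Members past the gene test were counted over all genes tested and adjusted over the list alone. With the correlation estimated from the data, the calls that hold are the AHR targets at the early time in each degron line and the immediate early genes and NF-kB targets in the NUP88 line at 2 h.

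The comparisons, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. Named are NUP214, NUP88, RANBP2 and RANGAP1, and the 10 largest rises and 10 largest falls by log2 change of each comparison of auxin with untreated cells and of RanGAP1 KR with WT. They had to pass the threshold, have a mean of at least 5 CPM and show no overlap between the libraries of both groups, so each named gene of these comparisons was higher or lower in 3 of 3 libraries. For late against early times and for differences between lines 5 and 5 are named, the differences without the condition on overlap. Small RNAs, pseudogenes, clone-type names, replication-dependent histones and sex-linked marker genes were left out. Of each list described, up to 2 members that rose and 2 that fell with the lowest adjusted p are named. Single-exon genes, gene types, genes shared between lines and the surroundings of CYP1A1 were chosen after the data were seen.

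Replicate numbers come from the sample titles. They were checked by the correlation, over genes, of the log2 CPM deviations from the group mean between libraries of the same number, and a comparison was taken as paired where each of its 3 correlations exceeded 0.1. This held for the 3 comparisons of the NUP214 line, for NUP88 at 2 h and 8 h against untreated and for RanBP2 at 4 h, and not for NUP88 8 h against 2 h, RanBP2 at 10 h against either group or RanGAP1. The count with the replicate number as a block is given beside the paired comparisons.

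The alternatives were DESeq2 1.42.0 with its Wald test, its size factors (RLE) in edgeR, no filter beyond 1 read, a stricter filter at a mean of 5 CPM, the replicate number as a block within a line, a fit of the compared lines alone, each library left out in turn, an estimated correlation for the lists and lists without shared members. Leaving out replicate 1 of a whole line, keeping only genes with a read in every line and the counts of single-exon genes were added after the data were seen. On data simulated from the NUP88 8 h comparison, edgeR recovered 42 of 80 genes changed 1.5-fold, 54 of 60 changed 2-fold and 60 of 60 changed 4-fold, with 7 false calls, 4.29% of its calls, while the fit with the replicate block made 14 false calls (8.43%) and DESeq2 20 (11%). The simulated counts held no effect of the replicate number, so they do not show the error of the block fit on paired libraries. Other splits of the libraries into groups of the same sizes were fitted in the same way, 10 per comparison of 3 with 3 libraries and 25 drawn for each difference between lines. No library was left out of the tests.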

Results

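RNA was sequenced from DLD-1, a human colorectal adenocarcinoma cell line, in which a nucleoporin of the cytoplasmic face of the nuclear pore could be degraded on demand. NUP214, NUP88 or RanBP2 carried an auxin-inducible degron, a tag that lets the plant hormone auxin trigger destruction of the tagged protein. By the sample titles the tag of NUP214 and NUP88 also held NeonGreen, which the titles of the RanBP2 line do not name. The 33 libraries form 11 groups of 3. NUP214 and NUP88 cells were untreated or held in 1 mM auxin for 2 h or 8 h, and RanBP2 cells were untreated or held in auxin for 4 h or 10 h. The last 2 groups are cells with FLAG-tagged RanGAP1, the GTPase-activating protein of Ran, in its wild-type (WT) form or in a form named KR. The depth was between 20.9 and 38.16 M counted reads per library, with a median of 31.24 M. The comparisons ask how gene expression changes after loss of each nucleoporin, whether the NUP88 and NUP214 lines respond alike, and how the RanBP2 line differs from them.

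The libraries fall into 2 sets by their reads on the mitochondrial genome. The RanBP2 and RanGAP1 libraries hold 0 reads on all 37 genes of the mitochondrial genome, while these genes take 0.318% to 1.57% of the reads in the NUP214 and NUP88 libraries. The first principal component, with 65.5% of the variance over 12339 genes, parts these sets. MT-CO1 has at least 17127 reads in each NUP214 and NUP88 library, so reads of these genes were left out of the other set before or at counting, and the sets were not mapped or counted alike. Each comparison below is therefore made within a line first, and lines are compared only through their changes from their own untreated libraries.

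The mRNA of a degron-tagged gene does not report on the amount of its protein, which is what auxin removes. In the NUP214 line NUP214 mRNA was 40.2 CPM ± 2.98 (SD, n = 3) untreated and 47.2 CPM ± 1.24 after 8 h. In the NUP88 line NUP88 mRNA was 120 CPM ± 7.49 untreated and 121 CPM ± 4.92 after 8 h, and in the RanBP2 line RANBP2 mRNA was 546 CPM ± 28.4 untreated and 485 CPM ± 52.5 after 10 h. None of these differences from the untreated cells passed edgeR's test (adjusted p = 0.164, 0.976 and 0.32). Between the auxin times, NUP214 mRNA in the NUP214 line rose (log2 change 0.34 ± 0.12, edgeR adjusted p = 0.0468) and NUP88 mRNA in the RanBP2 line fell (-0.26 ± 0.08, edgeR adjusted p = 0.0448), and both calls ended without 1 of several libraries, among them auxin 8 h replicate 1 for the former and auxin 10 h replicate 1 for the latter. RANGAP1 mRNA was 92.4 CPM ± 3.96 in the WT cells and 88.6 CPM ± 1.45 in the KR cells, with log2 change -0.06 ± 0.10 (SE).

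After 2 h of auxin in the NUP214 line, the largest rise was in CYP1A1, a cytochrome P450 that the aryl hydrocarbon receptor (AHR) induces, from 3.54 CPM ± 0.765 to 170 CPM ± 4.64 (log2 change 5.59 ± 0.48, SE, edgeR adjusted p = 8.41e-08). CYP1A1 (ENSG00000140465) lies on chromosome 15 at 74719542 to 74725610 in GRCh38. TIPARP, an ADP-ribosyltransferase induced by AHR, rose from 48.4 CPM ± 6.94 to 224 CPM ± 43.7 (log2 change 2.21 ± 0.12). IER3 (2.43 ± 0.33), the ERK phosphatase gene DUSP6 (1.54 ± 0.26), the cytokine gene GDF15 (2.02 ± 0.40) and the phosphatase subunit gene PPP1R15A (1.43 ± 0.16) rose as well. The largest falls were in ZBTB26 (-1.48 ± 0.18), ZNF552 (-1.39 ± 0.12), PPP1R3D, a glycogen-targeting phosphatase subunit (-1.39 ± 0.15), and HILPDA, a lipid droplet protein (-1.30 ± 0.13). FRAT2 (-1.29) and AMER1 (-1.18), both of the Wnt pathway, IER5 (-1.25), ZFP62 (-1.20) and ZNF749 (-1.16) fell as well. CYP1B1-AS1 (1.57), CYP1B1 (1.29), ADGRF1 (1.51) and OVOL1 (1.49) complete the rises, and IER5L (-1.24) the falls.

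Among the gene lists, 7 of the 12 measured AHR targets rose and 0 fell (8 rose when adjusted over the list alone), and the list rose by camera (adjusted p = 5.79e-23, and 0.000225 with an estimated correlation). Of 77 cytosolic ribosomal protein genes 11 rose and 0 fell, including FAU (0.34 ± 0.09), and 58 rose when adjusted over the list alone. That list's camera adjusted p was 5.11e-24 with the preset correlation and 0.947 with an estimated correlation. Of 30 immediate early genes 3 rose, including IER3 and KLF10 (1.03 ± 0.17), and IER5 and the antiproliferative BTG2 (-1.04 ± 0.21) fell. Adjusted over that list alone, 8 rose and 2 fell, and its camera adjusted p was 0.0147 and 0.978 with an estimated correlation. In all, 275 genes rose and 544 fell of 22167 tested at an edgeR adjusted p under 0.05, and 124 changed at least 2-fold. With the replicate number as a block 2870 genes passed, with DESeq2 1305 and with the NUP214 line fitted alone 149. Without auxin 2 h replicate 2 or 3, or without untreated replicate 3, the count was 537, 514 or 542. The make-up of the libraries moved in this comparison, with small RNAs from 4.29% ± 0.94 to 5.57% ± 1.04 of the reads, the top 10 genes from 6.40% ± 1.30 to 8.19% ± 1.27 and mitochondrial reads from 0.628% ± 0.231 to 0.361% ± 0.054. Untreated replicate 1 stood apart, with 4.9% of its reads on its top 10 genes and 0.886% on mitochondrial genes, and without replicate 1 of each group of this line 492 genes passed. The fit of the line alone ended the calls of GDF15, ADGRF1, OVOL1 and IER5L, and the last 3 also ended without 1 library (OVOL1 without auxin 2 h replicate 3 or untreated replicate 1, ADGRF1 without untreated replicate 3, IER5L without auxin 2 h replicate 1 or untreated replicate 2 or 3).

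After 8 h of auxin 4944 genes passed in the NUP214 line, against 3459 in the RanBP2 line at 10 h. The order reverses with each line fitted alone (2335 against 4866) and among genes changed at least 2-fold (884 against 1369). CYP1A1 stood at 66.4 CPM ± 12.4 (log2 change 4.23 ± 0.46), and TXNIP, an inhibitor of thioredoxin and glucose uptake, rose from 28.7 CPM ± 3.97 to 289 CPM ± 70.0 (3.33 ± 0.13, edgeR adjusted p = 1.24e-18). Its relatives ARRDC4 (2.32 ± 0.14) and ARRDC3 (1.91 ± 0.20) rose, as did the secreted lipase inhibitor ANGPTL4 (2.35 ± 0.27), RGS16 (2.16 ± 0.15), the transcription factor KLF11 (1.93 ± 0.15), the circadian repressor NR1D1 (1.79 ± 0.19), DUSP2 (1.72 ± 0.16) and NR6A1 (1.68 ± 0.16). The linker histone gene H1F0 fell from 93.6 CPM ± 28.4 to 21.0 CPM ± 0.2 (-2.16 ± 0.17), and MAGEF1 fell from 55.2 CPM ± 4.28 to 12.4 CPM ± 0.714 (-2.15 ± 0.08, edgeR adjusted p = 1.49e-19). RNF26 (-1.96), EID2 (-1.95), ZNF770 (-1.92), the selenophosphate synthetase SEPHS2 (-1.80), C4orf46 (-1.76), SPIN4 (-1.70) and CHMP1B-AS1 (-1.53) fell. NORAD, a noncoding RNA that binds Pumilio proteins, fell from 345 CPM ± 61.2 to 100 CPM ± 21.1 (-1.78 ± 0.13).

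At 8 h in this line 38 of 77 cytosolic ribosomal protein genes rose and 0 fell (58 and 0 adjusted over the list alone), with RPS7 at 0.38 ± 0.09. Of 36 ribosome biogenesis genes 17 rose, including the RNA polymerase I subunits POLR1C (0.78 ± 0.10) and POLR1B (0.59 ± 0.09), and RRS1 fell (-0.96 ± 0.13), with the same counts adjusted over the list alone. Of 45 measured KRAB zinc finger genes 15 rose and 6 fell (17 and 7 adjusted over the list alone), with ZNF30 at 1.30 ± 0.13 and ZNF33A at -1.02 ± 0.10. Of 30 immediate early genes 7 rose, led by MYC (1.46 ± 0.13) and DUSP2, and JUND (-0.99 ± 0.20) and MCL1 (-0.60 ± 0.14) fell. Of 18 TGF-beta and BMP targets 6 rose, including SMAD7 (0.87 ± 0.08) and TGIF1 (0.65 ± 0.08), and PMEPA1 fell (-1.15 ± 0.18), the same counts as over the list alone. Of 32 genes of G1/S and replication 4 rose and 7 fell, including FEN1 (-0.47 ± 0.10), and 4 rose and 8 fell adjusted over the list alone. Of 8 noncoding RNAs of a fixed list NORAD, OIP5-AS1 (-0.93 ± 0.13) and 1 other fell and 1 rose. Camera with the preset correlation called 13 of the 34 lists and with an estimated correlation 0, where the ribosomal protein list had adjusted p = 0.672 and the others named here 0.602 to 0.907. In all, 2513 genes rose and 2431 fell, 884 of them at least 2-fold, by edgeR. The blocked fit passed 7855 genes, and with the NUP214 line fitted alone 2335.

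Between 2 h and 8 h in the NUP214 line 1803 genes rose and 1626 fell, 532 of them at least 2-fold. TXNIP (log2 change 2.46 ± 0.12), KLF11 (1.88 ± 0.15), RGS16 (1.83 ± 0.14), ANGPTL4 (1.70 ± 0.25) and the circadian factor DBP (1.69 ± 0.29) had the largest rises. IER3 (-1.68 ± 0.31) and TIPARP (-1.53 ± 0.12), which had risen by 2 h, fell again. MAGEF1 (-1.73 ± 0.07), H1F0 (-1.63 ± 0.17) and RNF26 (-1.45 ± 0.14) fell in this interval. The blocked fit passed 6106 genes and the fit of this line alone 1277.

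**Figure D1:**
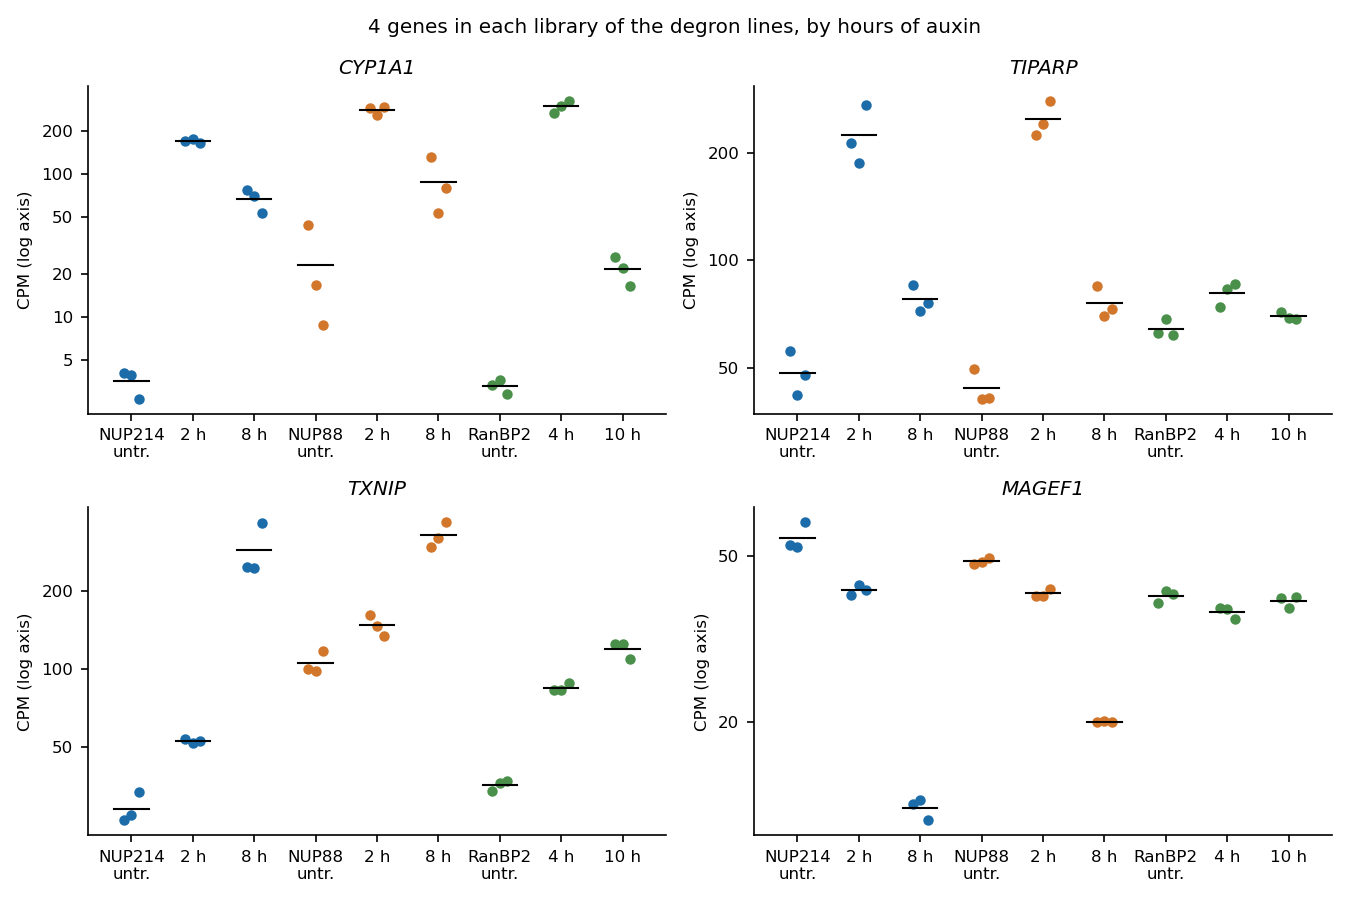
CPM (log axis) of CYP1A1, TIPARP, TXNIP and MAGEF1 in each library of the 3 degron lines (points) with the group mean (bar), by hours of auxin. CYP1A1 is higher after auxin in each line, TIPARP reaches 224 and 249 CPM at 2 h in the NUP214 and NUP88 lines, and MAGEF1 falls at 8 h in those lines.

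After 2 h of auxin in the NUP88 line CYP1A1 rose from 23 CPM ± 18.4 to 282 CPM ± 19.3 (log2 change 3.62 ± 0.42, edgeR adjusted p = 2.3e-05), and TIPARP from 43.9 CPM ± 4.95 to 249 CPM ± 28.1 (2.50 ± 0.13, adjusted p = 6.76e-15). IER3 (2.57 ± 0.34), the cell polarity gene PARD6B (1.85 ± 0.17), CYP1B1 (1.72 ± 0.19), CYP1B1-AS1 (1.67 ± 0.15), DUSP6 (1.65 ± 0.26), and the cytokine gene LIF (1.65 ± 0.21) rose. GDF15 (2.06 ± 0.40) and OVOL1 (1.73 ± 0.36) had calls that ended without auxin 2 h replicate 3 or untreated replicate 2 or 3, and that of OVOL1 also without untreated replicate 1. The falls were smaller: AMER1 (-0.84 ± 0.12), JRK (-0.81 ± 0.12), the homeobox gene HOXA13 (-0.73 ± 0.10), ZFP62 (-0.73 ± 0.11), HILPDA (-0.76 ± 0.12) and ZNF552 (-0.71 ± 0.11). Of 12 AHR targets 6 rose and 0 fell (7 and 0 adjusted over the list alone), with camera adjusted p = 5.9e-44 and 8.12e-07 with an estimated correlation. Of 30 immediate early genes 10 rose, including IER3 and KLF10 (1.11 ± 0.17), and IER5 fell (-0.64 ± 0.11), while 23 rose and 1 fell when adjusted over the list alone. That list rose by camera with adjusted p = 1.1e-33, and 0.00624 with an estimated correlation. The NF-kB target list also rose (adjusted p = 5.35e-09, and 0.0447 with an estimated correlation), with 1 of its 19 members past the test, NFKBIA (0.41 ± 0.10), and 5 adjusted over the list alone.

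By edgeR 93 genes rose and 59 fell in the NUP88 line at 2 h, 47 of them at least 2-fold. With the replicate number as a block 485 genes passed, with DESeq2 230, with no filter on low counts 285 and with the NUP88 line fitted alone 22. The count was 86 or 71 without auxin 2 h replicate 2 or 3, and 64 or 74 without untreated replicate 2 or 3. In the fit of the line alone the calls of IER3, GDF15, OVOL1, CYP1B1, DUSP6, LIF, HILPDA and ZNF552 ended. FRAT2 (-0.82), HOXA6 (-0.80), PPP1R3B (-0.74) and ZNF594 (-0.72), the other falls the rule names, each lost their call in that fit and without 1 or more of auxin 2 h replicates 1 to 3 or untreated replicates 2 and 3.

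After 8 h of auxin in the NUP88 line TXNIP rose from 105 CPM ± 11.1 to 331 CPM ± 36.7 (log2 change 1.65 ± 0.12, edgeR adjusted p = 7.79e-11) and CYP1A1 stood at 88.1 CPM ± 39.2 (1.95 ± 0.39). ARRDC4 (1.30 ± 0.13), the retinaldehyde dehydrogenase gene ALDH1A3 (1.28 ± 0.16), RGS16 (1.24 ± 0.15), SLC16A14 (1.23 ± 0.16), RND3 (1.17 ± 0.15), RGS2 (1.12 ± 0.23) and MYC (1.03 ± 0.13) rose. TCF4 (1.29 ± 0.28) rose with a call that ended without untreated replicate 2 or 3. The falls were led by H1F0 (-1.34 ± 0.17), MAGEF1 (-1.28 ± 0.07, from 48.5 CPM ± 0.75 to 19.9 CPM ± 0.0939), SPIN4 (-1.22 ± 0.13), the ubiquitin-binding UBQLN2 (-1.22 ± 0.14) and RNF26 (-1.16 ± 0.14). EID2 (-1.07), NORAD (-1.07 ± 0.13), PIGM, of GPI anchor synthesis (-1.07 ± 0.10), and the tight junction gene CLDN2 (-1.06 ± 0.18) fell too. SLC5A3 (-1.08 ± 0.27) lost its call without auxin 8 h replicate 2 or 3 or untreated replicate 1 or 2. The fit of the NUP88 line alone ended the calls of CYP1A1, TCF4, RGS2 and SLC5A3.

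Among the lists at 8 h in the NUP88 line, 9 of 36 ribosome biogenesis genes rose and 0 fell, including POLR1B (0.46 ± 0.09) and RRN3 (0.49 ± 0.10), and 18 rose and 1 fell when adjusted over the list alone. Of 27 mRNA export genes 5 rose and 0 fell (7 and 0 adjusted over the list alone), including the helicases DDX39B (0.43 ± 0.10) and DDX39A (0.49 ± 0.11). Of 30 immediate early genes 8 rose and 0 fell (10 and 1 adjusted over the list alone), led by MYC and DUSP2 (1.02 ± 0.16). Of 77 cytosolic ribosomal protein genes 0 passed over all genes or over the list alone, at a median log2 change of 0.19, where camera with the preset correlation gave adjusted p = 6.1e-11 and with an estimated correlation 0.426. Camera with an estimated correlation called 0 of the 34 lists, against 18 with the preset one, with adjusted p = 0.294 for ribosome biogenesis and immediate early genes and 0.255 for mRNA export. In all, 682 genes rose and 610 fell, 151 of them at least 2-fold. The blocked fit passed 3643 genes, and the fit of the line alone passed 504. The count was 750 without auxin 8 h replicate 2, and 487 or 780 without untreated replicate 2 or 3. Auxin 8 h replicate 3 stood apart, with 6.817% of its reads on small RNAs, against 4.231% and 4.032% in replicates 1 and 2. Its top 10 genes took 9.174% of the reads, against 6.211% and 5.977%. Untreated replicate 1 had 1.566% of its reads on mitochondrial genes, against 0.727% and 0.423% in replicates 2 and 3.

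Between 2 h and 8 h in the NUP88 line 151 genes rose and 165 fell, 54 of them at least 2-fold. TXNIP (log2 change 1.16 ± 0.12), SLC16A14 (1.06 ± 0.16), KLF11 (0.99 ± 0.14), ZFP36L1 (0.93 ± 0.16) and RGS16 (0.90 ± 0.15) had the largest rises, and TIPARP (-1.71 ± 0.12) and PIM1 (-1.31 ± 0.11) fell. CYP1A1 (-1.68 ± 0.38), IER3 (-1.58 ± 0.32) and the cell cycle inhibitor CDKN1A (-1.40 ± 0.31) fell with calls that ended without auxin 2 h replicate 3 or auxin 8 h replicate 2, among others. The count was 149, 182, 123 and 201 without auxin 2 h replicate 2 or 3 and auxin 8 h replicate 2 or 3. DESeq2 passed 535 genes and the fit of the line alone 73, in which SLC16A14, ZFP36L1, CYP1A1, IER3 and CDKN1A lost their calls.

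The responses of the NUP214 and NUP88 lines ran in the same direction. At 8 h 542 genes rose and 488 fell in both lines, where independent lists of these sizes would share 77.3 and 66.9, and 0 genes passed in opposite directions. Of the 1292 genes past the threshold in the NUP88 line, 98.1% had the same sign in the NUP214 line, with a median ratio of the NUP214 change to the NUP88 change of 1.19. Of the 4944 genes past the threshold in the NUP214 line, 91.9% had the same sign in the NUP88 line, with a median ratio of 0.46. Each ratio is pulled down for the line in which the genes were not selected. At 2 h 59 genes rose and 52 fell in both lines, where independent lists would share 1.15 and 1.45. The fallers in both lines at 2 h include AMER1, FRAT2, IER5, HILPDA, HOXA13, KCTD11 and ZNF552, chosen here after their values were seen.

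**Figure D2:**
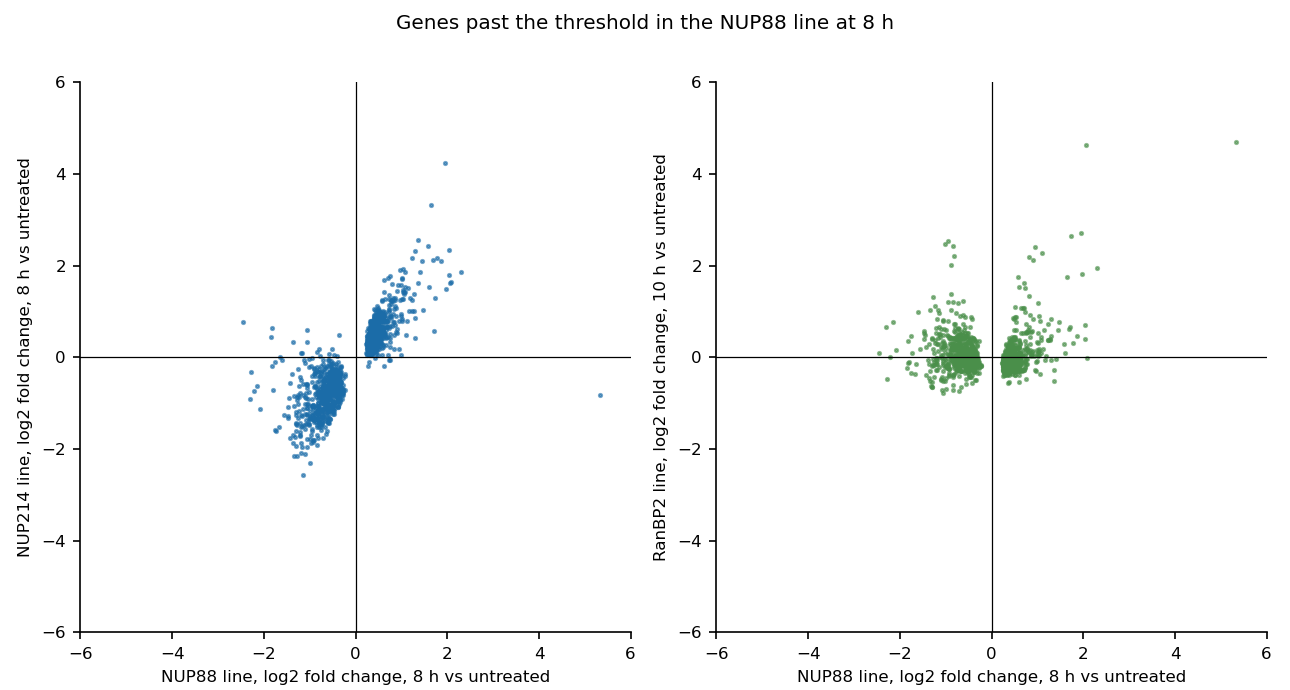
Log2 fold changes of the 1292 genes past the threshold in the NUP88 line at 8 h (x axis) against their log2 fold changes in the NUP214 line at 8 h (left) and in the RanBP2 line at 10 h (right), each point being 1 gene. In the NUP214 line 98.1% of them have the same sign.

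The test of the difference between the NUP88 and NUP214 responses found 0 genes at 2 h by edgeR, with 771 genes at an unadjusted p under 0.05. DESeq2 found 3, the fit with the replicate number as a block 13 and the fit with no filter on low counts 55. At 8 h 80 genes were higher and 25 lower in the NUP88 response, 13 of them by at least 2-fold. TXNIP (difference of log2 changes -1.68 ± 0.17, edgeR adjusted p = 5.87e-07) and ARRDC4 (-1.02 ± 0.18) rose less in the NUP88 line, and SFR1 (1.01 ± 0.18), KLHL23 (0.99 ± 0.18) and PNRC2 (1.06 ± 0.20) were higher in it. C4orf46 (1.06), BET1 (1.00), NR1D1 (-1.18), NR6A1 (-1.07) and CAMKK1 (-1.09) each lost their call without NUP88 untreated replicate 2, as did PNRC2, and in the fit of these lines alone TXNIP was the 1 named gene to keep its call. With the replicate number as a block 1283 genes passed at 8 h, with DESeq2 326 and with these lines fitted alone 2, so the number of genes that differ is poorly fixed. The count was 18 or 50 without NUP88 untreated replicate 2 or 3, 40 without NUP88 auxin 8 h replicate 1, 56 and 61 without NUP214 auxin 8 h replicate 2 and untreated replicate 1, and 169, 190 and 363 without NUP88 auxin 8 h replicate 3, NUP88 untreated replicate 1 and NUP214 untreated replicate 2.

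After 4 h of auxin in the RanBP2 line 35 genes rose, 26 of them at least 2-fold, and 0 fell by edgeR, with 1129 genes at an unadjusted p under 0.05 in either direction, and DESeq2 found 42 rises and 0 falls. CYP1A1 rose from 3.26 CPM ± 0.356 to 296 CPM ± 28.1 (log2 change 6.50 ± 0.50, edgeR adjusted p = 5.53e-08). CYP1B1-AS1 (1.98 ± 0.16), MEGF6 (1.84 ± 0.25), CYP1B1 (1.55 ± 0.20), TXNIP (1.25 ± 0.12), ALDH1A3 (1.16 ± 0.15), EDC3 (1.00 ± 0.14) and AHRR, the repressor of AHR (0.73 ± 0.10), rose. ITPR1 (1.08 ± 0.20) lost its call without auxin 4 h replicate 3 or untreated replicate 1 or 2, and SCIN (0.88 ± 0.15) without auxin 4 h replicate 1 or untreated replicate 1. Of 12 AHR targets 3 rose and 0 fell (6 and 0 adjusted over the list alone), with camera adjusted p = 2.51e-24 and 0.000128 with an estimated correlation. TIPARP was at 0.33 ± 0.12 (edgeR adjusted p = 0.694). With the replicate number as a block 78 genes rose and 3 fell, with no filter on low counts 74 passed and with the stricter filter 17. The count was 18 without auxin 4 h replicate 1 and 17 or 21 without untreated replicate 2 or 3.

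After 10 h of auxin in the RanBP2 line the rises and falls differed in kind. By edgeR 2162 genes rose and 1297 fell, and 1360 of the rises but 9 of the falls were at least 2-fold. Of the 3459 calls 1752 had a mean of at least 5 CPM, with 502 rises and 1250 falls among them, so most rises were in genes of low level. The balance among the better expressed genes depends on the fit, since with the stricter filter at a mean of 5 CPM 774 genes rose and 382 fell. The falls numbered 606 and 294 without auxin 10 h replicate 1 and 2 and 408 without untreated replicate 2, against 1544, 1271 and 1502 rises. TRPM5, a cation channel gene, rose from 0.988 CPM ± 0.13 to 11 CPM ± 3.91 (log2 change 3.48 ± 0.28). JUN (2.40 ± 0.25) and FOS (2.12 ± 0.27), which form the factor AP-1, rose to 53.6 CPM ± 8.51 and 25.3 CPM ± 3.6, and HES1, a Notch-responsive repressor, rose from 38.2 CPM ± 0.357 to 160 CPM ± 22.9 (2.06 ± 0.15, edgeR adjusted p = 3.73e-11). CYP1A1 (2.72 ± 0.47), CYP1B1-AS1 (2.19 ± 0.16), KRTAP3-1 (2.16 ± 0.22), the noncoding RNAs MIAT (2.11 ± 0.20) and LINC00513 (2.08 ± 0.25), and TXNIP (1.75 ± 0.12) rose too. The largest falls were in TXNRD1, thioredoxin reductase (-0.82 ± 0.10, from 511 CPM ± 32.9 to 290 CPM ± 25.5), CTNNAL1 (-0.74 ± 0.13), the decoy receptor gene IL1R2 (-0.70 ± 0.14), ARID5B (-0.68 ± 0.13), GCNT1 (-0.65 ± 0.11), GPAT3 (-0.65 ± 0.13), RRM1-AS1 (-0.65 ± 0.13) and RAB3B (-0.64 ± 0.13). CAVIN1 (-0.66 ± 0.16) lost its call without auxin 10 h replicate 2, and TAGLN (-0.66 ± 0.21) without auxin 10 h replicate 1 or 2 or untreated replicate 1 or 2. NUP88 mRNA fell from 171 CPM ± 12.3 to 127 CPM ± 8.0 (-0.43 ± 0.08, edgeR adjusted p = 0.000328).

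By gene type 334 of 1280 long intergenic noncoding RNA genes, 506 of 2744 antisense genes and 128 of 281 small nucleolar RNA genes rose in the RanBP2 line at 10 h, while 771 protein-coding genes rose and 1168 fell. The make-up of the libraries moved as well, from untreated to 10 h: small RNAs went from 5.15% ± 0.40 to 7.37% ± 0.46 of the reads and the 10 genes with the most reads from 7.29% ± 0.43 to 9.85% ± 0.55. In the NUP214 line small RNAs reached 6.21% ± 0.65 at 8 h, the top 10 genes 8.86% ± 0.88 and mitochondrial reads 0.353% ± 0.050, and 59 of the 281 small nucleolar RNA genes rose and 4 fell. Reads of an antisense gene cannot be parted from those of its partner here, since the labels do not state that counting used strand. Of 17 host genes of small nucleolar RNAs 8 rose and 0 fell (10 and 0 adjusted over the list alone), including SNHG5 (0.72 ± 0.11) and ZFAS1 (0.56 ± 0.09). Of 30 immediate early genes 11 rose and 0 fell (13 and 0 adjusted over the list alone), led by the phosphatase gene DUSP1 (1.54 ± 0.14) and JUN. Of 32 genes of G1/S and replication 11 fell and 0 rose (15 and 0 adjusted over the list alone), including PCNA (-0.48 ± 0.09) and RRM1 (-0.42 ± 0.08). Of 23 scaffold and basket nucleoporin genes 9 fell and 0 rose (12 and 0 adjusted over the list alone), including NUP107 (-0.41 ± 0.08) and NUP133 (-0.34 ± 0.08). Of 19 heat shock genes 7 fell (8 adjusted over the list alone), including HSP90AB1 (-0.46 ± 0.10) and HSP90AA1 (-0.60 ± 0.12), and of 18 NRF2 targets 5 fell (9 adjusted over the list alone), including TXNRD1 and GCLC (-0.39 ± 0.09), with 0 rises in either list. Camera called 16 lists with the preset correlation and 0 with an estimated one, where the lists named here had adjusted p = 0.32, 0.327, 0.345, 0.239, 0.345 and 0.239 in this order. The count of genes was 2150 or 1565 without auxin 10 h replicate 1 or 2 and 1910 without untreated replicate 2, and with the stricter filter 1156 genes passed.

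Between 4 h and 10 h in the RanBP2 line 1213 genes rose and 274 fell, 771 and 9 of them at least 2-fold, and at a mean of at least 5 CPM 258 rose and 250 fell. The balance at that level may depend on the filter, as it did for 10 h against untreated. KRTAP3-1 (log2 change 2.40 ± 0.23), JUN (2.10 ± 0.25), FOS (2.02 ± 0.27), TRPM5 (1.81 ± 0.24) and HES1 (1.73 ± 0.15) rose. CYP1A1 fell back (-3.78 ± 0.42), as did EDC3 (-0.77 ± 0.14) and DENND3 (-0.77 ± 0.14), while the falls of NANOS1 (-0.94 ± 0.28) and MEGF6 (-0.78 ± 0.23) lost their calls without auxin 10 h replicate 1 or auxin 4 h replicate 1 or 2, among others. The count was 783, 651 and 2367 without auxin 10 h replicate 1, 2 and 3, 823 and 816 without auxin 4 h replicate 2 and 3, and 383 with the stricter filter.

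**Figure D3:**
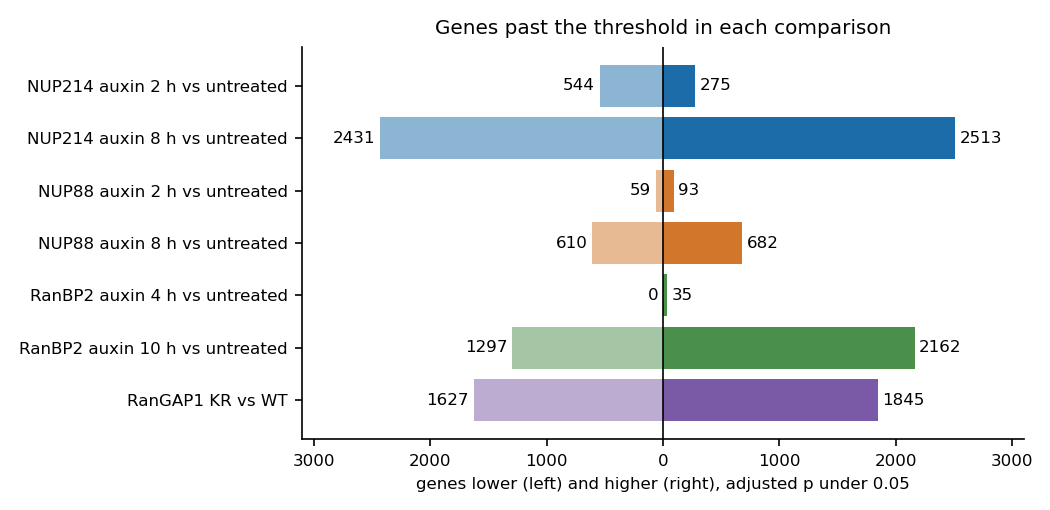
Number of genes higher (right) and lower (left) at an edgeR adjusted p under 0.05 in each comparison of auxin with untreated cells and of RanGAP1 KR with WT, out of 22167 genes tested. The NUP214 line at 8 h has 2513 genes higher and 2431 lower, and the RanBP2 line at 4 h has 35 higher and 0 lower.

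The RanBP2 response was set against the mean of the NUP214 and NUP88 responses. The times of auxin differ (4 h against 2 h, 10 h against 8 h), and so do the tags named in the titles, so line, tag and time are not separated. Early, 96 genes were higher and 26 lower in the RanBP2 response, 35 of them by at least 2-fold. IER3 (difference of log2 changes -2.30 ± 0.38), TIPARP (-2.02 ± 0.15, edgeR adjusted p = 2.77e-10), PARD6B (-1.44 ± 0.20) and the kinase gene PIM1 (-1.34 ± 0.14) were lower, and PPP1R3D (1.08 ± 0.18), AMER1 (1.05 ± 0.15) and PPP1R3B (1.05 ± 0.19) were higher. DUSP6 (-1.47 ± 0.32), KSR2 (1.19 ± 0.28) and ZBTB26 (1.11 ± 0.22) lost their calls without RanBP2 untreated replicate 2, among others. CYP1A1 differed by 1.89 ± 0.54 (edgeR adjusted p = 0.134). With the replicate number as a block 594 genes passed, with DESeq2 251, with no filter on low counts 199, with the stricter filter 186 and with these lines fitted alone 64. The count was 54, 51 and 77 without RanBP2 untreated replicate 1, 2 and 3, 57, 67 and 66 without RanBP2 auxin 4 h replicate 1, 2 and 3, 77 without NUP88 untreated replicate 2 and 248 without NUP214 untreated replicate 1.

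Late, 2670 genes were higher and 2438 lower in the RanBP2 response. At least 2-fold, 1517 were higher and 67 lower, and at a mean of at least 5 CPM 993 were higher and 2315 lower, so in this fit the balance turns with level and size. It may also depend on the filter, as the balance in the RanBP2 line at 10 h did. AHNAK2 (3.34 ± 0.47), BAHCC1 (2.96 ± 0.51), LINC00513 (2.27 ± 0.30) and RNF26 (1.86 ± 0.17, edgeR adjusted p = 1.15e-08) were higher, and ADGRF1 (-1.88 ± 0.39), ARRDC3 (-1.74 ± 0.23), RGS16 (-1.33 ± 0.18), ZNF57 (-1.27 ± 0.13) and MAP6D1 (-1.22 ± 0.20) were lower. Of 77 cytosolic ribosomal protein genes 36 were lower and 0 higher (39 and 0 adjusted over the list alone), including RPL5 (-0.52 ± 0.11), and of 36 ribosome biogenesis genes 17 were lower, including RRN3 (-0.78 ± 0.12) and POLR1B (-0.71 ± 0.11), and RRS1 (0.75 ± 0.15) was higher (19 and 1 adjusted over the list alone). Of 8 noncoding RNAs of a fixed list 5 were higher and 0 lower, over all genes and over the list alone, including MIAT (1.90 ± 0.25) and NORAD (1.14 ± 0.15). Of 27 mRNA export genes 10 were lower and 0 higher (14 and 0 adjusted over the list alone), including DDX39A (-0.74 ± 0.14) and DDX39B (-0.57 ± 0.12). With an estimated correlation these lists had camera adjusted p = 0.416, 0.301, 0.25 and 0.218. NUP88 mRNA was lower by its own test (-0.44 ± 0.10, edgeR adjusted p = 0.00179). The count of genes was 3219 without RanBP2 auxin 10 h replicate 2 and 2841 with the stricter filter.

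At the late time 42 genes rose and 28 fell in all 3 lines, where independent lists of these sizes would share 7.54 and 3.91. The lists are not independent, and given the genes that the NUP214 and NUP88 lines share, a RanBP2 list of this size would take in 52.9 and 28.6, so the late overlap of all 3 lines is no larger than that. The shared rises include CYP1A1, TXNIP, ARRDC4, the zinc finger factors KLF4, KLF10 and KLF11, DUSP1, SMAD7, TGIF1, SGK1, SNAI1 and PPP1R15A, and the shared falls include BRCA1, CD24, DDX3X, SP1, RBBP4 and RAB3B. These names were chosen after their values were seen. Between the NUP214 and RanBP2 lines 494 of the 708 genes past the threshold in both changed the same way and the others in opposite directions, and between the NUP88 and RanBP2 lines 83 the same way and 114 in opposite directions. At the early time 12 genes rose in all 3 lines, where 0.0932 would be expected given the genes that the NUP214 and NUP88 lines share. They are CYP1A1, CYP1B1, CYP1B1-AS1, AHRR, ALDH1A3, TXNIP, ARRDC4, EDC3, CLK3, TPRA1, STMND1 and AC015712.2. EDC3 and CLK3 overlap on opposite strands near CYP1A1, so these need not be separate responses. The late count of 70 genes was 7 without replicate 2 of each line and 44 without replicate 3. With the replicate number as a block it was 315, with 144 rises where 202 are expected given the genes shared by the NUP214 and NUP88 lines, and 171 falls where 157 are.

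Protein-coding genes of few exons fell more often than others in the NUP214 and NUP88 lines, a result looked for only after the data were seen. Of 178 genes of 1 exon with a mean over 1 CPM, replication-dependent histone genes left out, 59 fell and 0 rose at 2 h and 83 fell and 7 rose at 8 h in the NUP214 line, by edgeR. In the NUP88 line 14 fell and 1 rose at 2 h and 54 fell and 1 rose at 8 h. A wider set keeps replication-dependent histone and Y-linked genes, at the same cut of 1 CPM. In it the 59 and 14 falls at 2 h became 19 and 1 with each line fitted alone. The 14 falls in the NUP88 line became 24 with DESeq2 and 37 with the replicate number as a block. With that block its 55 falls at 8 h became 86. Of the 178 genes 0 fell and 1 rose at 4 h in the RanBP2 line, and 0 fell and 37 rose at 10 h. The median log2 change was -0.47 in the NUP214 line at 8 h, -0.28 in the NUP88 line at 8 h and 0.14 in the RanBP2 line at 10 h. In the test of the difference between the late responses 97 of these genes were higher and 2 lower in the RanBP2 line. The change is graded over exon number rather than a trait of single-exon genes: at 8 h in the NUP214 line 46.6% of genes of 1 exon, 39% of the 351 of 2 exons, 22.1% of those of 3 to 4 and 9.38% of those of 9 or more fell, and in the NUP88 line 30.3%, 12.8%, 5.51% and 1.63%. Of the genes of 2 exons 111 were higher and 12 lower in the late RanBP2 difference. Of the genes named above as falling in the NUP214 or NUP88 line, MAGEF1, H1F0, SPIN4, RNF26, EID2, SEPHS2, UBQLN2, PIGM, PPP1R3D, IER5, IER5L, FRAT2, KCTD11, RRS1 and the noncoding NORAD have a single annotated exon, and of those named in the RanBP2 line, so do JUN, which rose, and NANOS1.

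**Figure D4:**
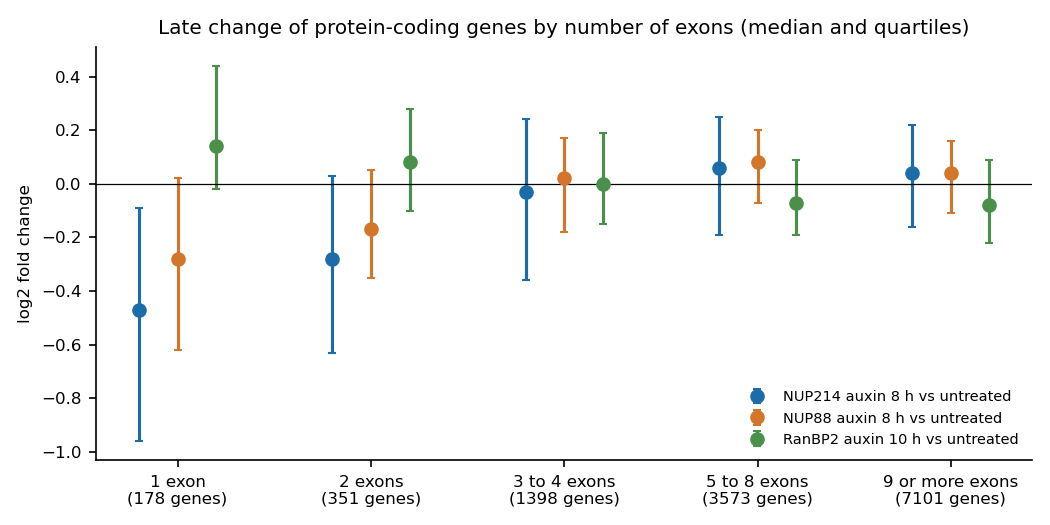
Log2 fold change (y axis) of protein-coding genes by their number of exons (x axis, number of genes below each class) in the NUP214 line at 8 h, the NUP88 line at 8 h and the RanBP2 line at 10 h. Points are medians and bars run from the lower to the upper quartile, and for the 178 genes of 1 exon the medians are -0.47, -0.28 and 0.14.

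Cells with RanGAP1 KR differed from cells with RanGAP1 WT in 3472 genes, 1845 higher and 1627 lower in KR by edgeR, with 371 and 700 at least 2-fold. With RLE size factors 1709 were higher and 1784 lower, so the balance depends on the scaling. Each form is represented by 1 set of cells in the labels, so a difference between the forms and a difference between the sets of cells cannot be told apart. ZNF141 rose from 2.06 CPM ± 0.143 to 28.4 CPM ± 1.0 (log2 change 3.78 ± 0.17, edgeR adjusted p = 6.84e-17), the matrix metalloproteinase gene MMP14 from 1.62 CPM ± 0.2 to 17.2 CPM ± 1.66 (3.41 ± 0.23) and the calcium sensor gene VSNL1 to 14.1 CPM ± 1.68 (3.23 ± 0.16). CC2D2A (3.09), BEND7 (2.96), APOL1 (2.58), the stress kinase gene MAPKAPK3 (2.54 ± 0.10, 109 CPM ± 3.55 in KR), GALNT5 (2.45), STAP2 (2.27) and the adhesion gene CADM1 (2.20) were higher too. ADGRL2, latrophilin 2, on chromosome 1 at 81306160 to 81992436, had 28.5 CPM ± 1.54 in WT and 0 reads in the 3 KR libraries. Against a floor of 3 reads over the KR group, 0.0286 CPM, it was at least 998-fold lower. RPS6KA6, the kinase RSK4, had 1801 reads in the WT libraries and 1 in the KR libraries, a ratio of 2220 with a 95% counting interval from 397 to 87600. The other largest falls lie in 1 locus, the UGT1A genes for glucuronidation on chromosome 2, whose shared exons mean that the reads cannot be assigned to a member with certainty. UGT1A1 went from 28.3 CPM ± 1.22 to 0.0668 CPM ± 0.0169, with 7 reads in the KR libraries, and UGT1A3, UGT1A4, UGT1A5, UGT1A7, UGT1A8, UGT1A9 and UGT1A10 had 7 or 8.

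Of 34 G2/M genes 14 were higher and 0 lower in RanGAP1 KR (18 and 0 adjusted over the list alone), including the phosphatase gene CDC25C (1.19 ± 0.14) and the kinesin gene KIF20A (0.65 ± 0.10). Of 53 replication-dependent histone genes 26 were higher and 0 lower (40 and 0 adjusted over the list alone), including HIST1H2AI (0.76 ± 0.12) and HIST2H2BF (0.68 ± 0.11). Of 17 intestinal epithelium genes 8 were lower and 0 higher (11 and 0 adjusted over the list alone), including the cadherin gene CDH17 (-1.68 ± 0.18) and the keratin gene KRT18 (-0.77 ± 0.13). Of 19 NF-kB targets 8 were higher, including the chemokine genes CXCL3 (3.6 ± 0.25) and CXCL2 (1.85 ± 0.28), and TNFAIP2 (-3.97 ± 0.83, mean 0.11 CPM) and ICAM1 (-0.42 ± 0.10) were lower (11 and 2 adjusted over the list alone). Of 24 interferon response genes 7 were higher, including MX1 (1.03 ± 0.13) and IFIT3 (1.00 ± 0.18), and DDX58 (-0.84 ± 0.13) and OAS2 (-1.13 ± 0.31) were lower (8 and 2 adjusted over the list alone). Camera called 5 lists with the preset correlation and 0 with an estimated one, where these lists had adjusted p = 0.624, 0.955, 0.624, 0.624 and 0.968. With the RanGAP1 libraries fitted alone 6496 genes passed.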

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

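The tests of single-exon genes, of the AHR targets, of an even background, of transcription past gene ends as a part of the rise and of other splits were chosen only after the result was seen, while those of transcription past gene ends as the whole cause, of 1 library and of neighbouring genes in the RanBP2 line were written before.

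In 4 results a test of the difference itself called genes in the fit over all libraries: 105 genes between the NUP88 and NUP214 responses at 8 h, 122 genes between the RanBP2 response and the mean of the others early and 5108 late, and 97 single-exon genes higher in the RanBP2 response late. The count of 105 is poorly fixed, at 18 to 363 with a library left out, and the splits below cannot exclude chance for differences between lines. Outside the genes tested, the 5268 protein-coding genes below the count filter took 203 CPM ± 46.5 (SD, n = 3) in the RanBP2 line at 10 h, 126 CPM ± 12.2 at 4 h and 101 CPM ± 8.76 untreated. An exact two-sided permutation test of 10 h against untreated gave p = 0.1, the smallest possible p for 3 against 3 libraries.

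Single-exon genes fell in the NUP214 and NUP88 lines, 83 and 54 of 178 at 8 h, and rose or did not pass in the RanBP2 line. Genes of 2 exons fell too, 137 and 45 of 351 at 8 h. Expression level and exonic length are argued against, since the lowest median among 10000 lists of multi-exon genes matched for both was -0.05 in the NUP214 line at 8 h, against -0.47 for the single-exon genes. Exonic length spans all annotated exons of a gene, so the length of the expressed transcript was not matched. Genomic DNA in the untreated libraries is argued against by a loss per kb at least 2350 times that over olfactory receptor genes. The genes compared were those that fell, which makes this ratio large, but olfactory receptor genes lost only 0.000436 (NUP214) and 0.00122 (NUP88) CPM per kb. A fall from auxin itself was not seen in the RanBP2 line, with medians of 0 at 4 h and 0.14 at 10 h. No line without a degron was treated with auxin, so an opposite effect of RanBP2 loss that hides such a fall cannot be excluded. A preparation that raises the share of small RNAs, which rose in the NUP214 line, stays open for that line and for the NUP88 line at 8 h. For the NUP88 line at 2 h it is argued against, since the share was 4.49% ± 0.32 untreated and 4.44% ± 0.55 at 2 h. The median of the single-exon genes was -0.21 there, against -0.03 for the lowest matched list, though only 14 of the 178 passed as falls. The share of small RNAs also rose by 2.23 percentage points in the RanBP2 line at 10 h, where the single-exon genes did not fall. However, those libraries were not mapped or counted like the NUP214 and NUP88 ones, and a difference in preparation stays open for them too. A candidate explanation, untested here, is that export or stability of transcripts with few or no introns may depend more on NUP214 and NUP88 than on RanBP2. Differences between the lines in other respects stay open, since each protein was tagged in 1 line.

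AHR targets rose early in the 3 degron lines, with CYP1A1 the largest rise in each. An effect of auxin itself, which may act on AHR without any degradation, cannot be told apart from loss of the nucleoporins: the lowest early log2 change of CYP1A1 was 3.62, and no line without a degron was treated with auxin among these samples. The early times also differ, 2 h in the NUP214 and NUP88 lines and 4 h in the RanBP2 line.

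Noncoding and low-count genes rose in the RanBP2 line at 10 h. An even background such as genomic DNA is argued against by a median gain per kb 537 times that over olfactory receptor genes. The genes compared were chosen for having risen 2-fold, which by itself makes this ratio large. Reads over olfactory receptor genes did rise, from 0.00319 to 0.0036 CPM per kb in the untreated libraries to 0.0042 to 0.0061 at 10 h. That gain, 0.00176 CPM per kb between the means, is small beside the median gain of 0.946. Transcription running past the ends of expressed genes is argued against as the whole cause, since 13.8% of low-count genes past a 3' end rose 2-fold against 26.4% of those before a 5' end. As a part it stays open: of genes near no expressed gene 7.92% rose, fewer than past a 3' end, while past a 3' end 12.3% rose on the same strand and 15.8% on the opposite one. The work of 1 library is argued against, since at least 903 genes rose 2-fold with any 10 h library left out (903 without replicate 2, 1360 with all). Higher activity of the neighbouring gene is argued against for low-count genes before a 5' end only. There the median log2 changes of the neighbours of the 223 that rose and of the 622 others differed by 0.01. Low-count genes in other places were not tested for it. A candidate explanation, untested here, is that slower turnover of RNA made upstream of promoters may raise these genes. Of those before a 5' end 165 of 223 that rose and 377 of 622 others lie on the opposite strand, and the strand of counting is not given in the sources used here. The share of small RNAs rose in the same libraries, and a difference in their preparation, which would coincide with the groups, stays open.

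For comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave the highest count of genes in each. In the NUP214 line the real counts were 819 at 2 h, 4944 at 8 h and 3429 between them, and the highest other splits gave 806, 836 and 55. At 2 h the split with 806 follows replicate number 1, and with the replicate number as a block 2870 genes passed. In the NUP88 line the real counts were 152, 1292 and 316 against 2, 52 and 0 in the highest other splits. In the RanBP2 line they were 35, 3459 and 1487 against 0, 47 and 180, and for RanGAP1 3472 against 0.

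Among 25 splits of the libraries, 1 split, the real one, was as large for the RanBP2 response against the mean of the others early (122, highest other 10) and late (5108, highest other 3758). The splits shuffle auxin and untreated libraries within each line, so they ask whether auxin had an effect and not whether the lines differ in it. They therefore cannot exclude chance for a difference between lines. For the 70 genes changed alike in the 3 lines (1 split as large, highest other 3) the splits decide nothing, since most call few genes in a line, and 81.4 genes are expected given those shared by the NUP214 and NUP88 lines. For the NUP88 response against the NUP214 response at 2 h the real count was 0, which each of the 25 splits reaches, so they decide nothing (highest other 17). At 8 h 4 splits, the real one included, gave at least the real count of 105 (highest other 2463), so chance cannot be excluded. These splits ignore the replicate numbers, which pair the libraries of both lines at 8 h, and with the number as a block 1283 genes passed. The 3 other splits with at least 105 genes differ in kind. Those with 2463 and 729 genes hold the 3 NUP214 auxin libraries together, and that with 3758 genes the 3 RanBP2 auxin libraries, so these retain the auxin response of a line. The split with 862 genes follows replicate numbers, with both NUP214 libraries of number 2 set against both of number 3 and both NUP88 libraries of number 1 against both of number 2.

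Counts of lists varied more between splits. With 10 splits, too few for a share under 0.05, the real counts for NUP214 were 8, 13 and 9 with 7, 4 and 7 splits as large (highest other 15, 18 and 16). For NUP88 they were 16, 18 and 12 with 1, 1 and 4 (14, 14 and 14), for RanBP2 11, 16 and 12 with 1, 1 and 4 (8, 14 and 13), and for RanGAP1 5 with 7 (9). With 25 splits chance cannot be excluded for the NUP88 response against the NUP214 response at 2 h (8 lists, 20 splits as large, highest other 17). Nor can it be for the late RanBP2 difference (17 lists, 4 splits, 20). For NUP88 against NUP214 at 8 h the real count was 0 lists, which each of the 25 splits reaches, so they decide nothing (highest other 18). For the early RanBP2 difference 1 split, the real one, was as large with the preset correlation (16 lists, highest other 14). These splits cannot decide whether the lines differ there, and 0 lists passed with an estimated correlation.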

How the results depend on the processing

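Leaving out replicate 1 of a whole line, keeping only genes read in every line and recounting the single-exon genes were chosen only after the result was seen. With DESeq2 the count of genes moved to 1305 (NUP214 2 h), 230 (NUP88 2 h), 535 (NUP88 8 h against 2 h), 3 and 326 (NUP88 minus NUP214 at 2 h and 8 h) and 251 (early RanBP2 difference). Fits of the compared lines alone gave 149, 2335 and 1277 (NUP214 2 h, 8 h, 8 h against 2 h), 22, 504 and 73 (NUP88), 6496 (RanGAP1), 2 (NUP88 minus NUP214 at 8 h) and 64 (early difference). The fit over all libraries pools spreads that differ between lines, with a median SD of log2 CPM of 0.072 and 0.082 in the RanGAP1 groups and 0.134 to 0.205 in the NUP214 groups.

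The replicate block gave 2870, 7855 and 6106 (NUP214), 485, 3643 and 1171 (NUP88), 81, 6083 and 3078 (RanBP2), 5680 (RanGAP1), 13 and 1283 (NUP88 minus NUP214), 594 and 7937 (early and late differences) and 315 genes in all 3 lines. The cause was not tested. No filter gave 285 (NUP88 2 h), 74 (RanBP2 4 h), 55 and 381 (NUP88 minus NUP214) and 199 (early). The stricter filter, with fewer genes tested, gave 17, 1156 and 383 (RanBP2), 215 (NUP88 minus NUP214 at 8 h), 186 (early) and 2841 (late). Without replicate 1 of the line the counts were 492 (NUP214 2 h), 837 (NUP88 8 h) and 190 (NUP88 8 h against 2 h). RLE moved no count by over 1.5 times. The single-exon recount kept replication-dependent histone and Y-linked genes, unlike the set in the report, at the same cut on level. Falls at 8 h were 87 (NUP214) and 55 (NUP88), against 71 and 45 in fits of the compared lines alone and 110 and 86 with the block. At 2 h fits of the compared lines alone gave 19 (against 59) and 1 (against 14).

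With each library left out in turn, the counts ranged over 514 to 922, 3469 to 5342 and 2487 to 3400 (NUP214), 64 to 206, 487 to 1333 and 123 to 322 (NUP88), 17 to 31, 1565 to 4671 and 651 to 2367 (RanBP2), 2503 to 2749 (RanGAP1), 0 to 1 and 18 to 363 (NUP88 minus NUP214), 51 to 248 and 3219 to 5970 (early and late) and 7 to 48 (3 lines, a replicate number left out of each).

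Camera with an estimated correlation called 1, 0 and 0 lists (NUP214), 3, 0 and 0 (NUP88), 1, 0 and 0 (RanBP2) and 0 for RanGAP1, for NUP88 minus NUP214 at 2 h and for both RanBP2 differences. With the block 1 list passed for NUP88 minus NUP214 at 8 h, against 0. Of the list calls 5 of 161 held with an estimated correlation and 1240 of 1410 with a library left out.

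Of the calls of named genes 726 of 729 held with DESeq2, 718 of 732 with RLE, 730 of 732 with the block, 546 of 728 in fits of the compared lines alone and 4994 of 5760 with a library left out, and 0 reversed. At this depth edgeR recovered 42 of 80 simulated 1.5-fold changes and 54 of 60 simulated 2-fold changes, so changes under 2-fold are detected in part.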

Other observations

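The genes around CYP1A1 were looked at only after its values were seen. Within 200 kb on chromosome 15, EDC3, 23.2 kb away, rose in each degron line at the early time, with log2 changes of 0.78 (NUP214), 1.02 (NUP88) and 1.00 (RanBP2), and CLK3, 74.1 kb away, with 0.88, 0.89 and 0.57 (edgeR adjusted p = 2.14e-06, 4.35e-06 and 0.00692). EDC3 lies past the 3' end of CYP1A1 on the same strand. CLK3 ends at 74645414 and EDC3 starts at 74630558 on the opposite strand, so they overlap. As the strand of counting is not given, their rises need not be separate. On the other side of CYP1A1, CYP1A2, 23.2 kb away, passed in the NUP214 line (2.40, edgeR adjusted p = 0.00854) and not in the NUP88 line (1.59, 0.91) or the RanBP2 line (2.15, 0.232). CSK, 56.4 kb away, passed in the RanBP2 line (0.58, edgeR adjusted p = 0.00612), and FAM219B, 174 kb away, was lower in the NUP214 line (-0.64, 0.0128). Whether these changes differ between the lines was not tested for each gene.

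Between the libraries of the RanBP2 and RanGAP1 cells and those of the NUP214 and NUP88 cells, 39 genes had 0 reads in the former and over 30 reads in each of the latter, 27 of them on the mitochondrial genome and 12 on the X chromosome, and 22 genes the other way round. KRTAP3-1, named above as a rise within the RanBP2 line, is among the 22, so that rise cannot be set against the NUP214 and NUP88 lines. The 12 on X lie near the ends of that chromosome, among them SLC25A6 with at least 5673 reads in each NUP214 and NUP88 library. As the sets were not mapped or counted alike, these zeros need not be differences between the cells.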
